A study of Homo sapiens with 6 samples.

How the data were processed

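The data are 6 poly(A) RNA sequencing libraries of primary rheumatoid arthritis synovial fibroblasts, 3 transfected with a control siRNA and 3 with a pooled DLX4 siRNA, grouped and lettered by their titles in the labels. Per the labels' protocols, cells were kept 24 to 48 h after transfection, 400 ng of total RNA per sample was sent for library preparation with poly-T beads, and paired-end Illumina reads were made. The authors deposited 1 table of FPKM values, 57905 Ensembl gene IDs by 6 libraries, that is fragments per kilobase of gene, scaled to the depth of the library. Per the submitters' processing notes, the genome build was hg19 and CASAVA was used. The aligner, the counting tool, the annotation, the strand setting and any filter are not given in the sources used here. FPKM removes depth and gene length, so a value carries neither the number of fragments behind it nor any correction for differences in composition between libraries.

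Gene symbols were matched by Ensembl ID to a name table (51996 IDs found, 39538 with a symbol), and transcript sequences and lengths to GENCODE release 29 (52338 IDs found). That annotation belongs to another genome build than the one named in the notes, so only IDs, names and transcript sequences were used and no coordinates are given. Y-linked genes and XIST (474 IDs) were left out.

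Depth was recovered from the values. Where whole fragments were counted, the values of a gene are whole multiples of what 1 fragment is worth. Among low single-exon genes 89.0% to 91.6% of the values per library came out whole within a tolerance of 0.05, where 10% would by chance, at depths of 19.6 to 25.2 M fragments (M, mega). Ratios between libraries then gave whole fragments for 14209 of 14250 genes with a mean of at least 0.5 FPKM (99.7%, tolerance 0.02). Intervals and floors from such counts cover counting error only. The libraries were compared in pairs on these fragments. The chi-square per degree of freedom was 2.73 between controls a and b, 2.77 between DLX4 siRNA b and c, and 14.0 to 39.0 between other pairs. No pair thus differed by counting noise alone, which cannot show whether the libraries came from separate cultures.

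The test was limma 3.58.1 in R 4.3.3 (linear fit, empirical Bayes with a trend) on log2(FPKM + 1), with the group as the only term, over the 14237 genes with a mean of at least 0.5 FPKM, DLX4 always kept. The threshold was a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Folds and means ± SD are of FPKM. DLX4 also had an exact two-sided permutation test and a conditional exact interval of its fragment ratio. Of 40 gene lists fixed before the data were examined, the 35 with at least 5 tested members were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry, which asks whether a list's genes move one way on balance and compares no lists. With an estimated correlation none of the 10 camera calls held.

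The rule for naming genes picked DLX4 and the other DLX genes, the 12 highest and 12 lowest fold changes among called genes with a symbol (the deposited table gives no biotype), a mean of at least 1 FPKM and groups that do not overlap, up to 4 called members with the smallest p of each list (2, as values, where none passed), and 19 genes fixed in advance. Some list members that it picked, such as INSIG1, NT5E and FGF5, are not described below, and the rule did not decide which. This rule, the lists, the test and the following alternatives were set before the data were examined. The alternatives were pseudocounts of 0.1 and 0.5, no level filter and filters at 1 and 5 FPKM, rescaling to the same sum, median-ratio scaling, quantile normalization, limma without the trend, robust and with array weights, a replicate block, protein-coding genes alone, each library left out, an estimated correlation, and stricter thresholds. Added after seeing the data were fits without control c and DLX4 siRNA a, with a term for them, on genes with no CCATCT in any annotated transcript, and with voom on the recovered fragments.

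Words of 7 bases in 3′ UTRs (per gene the GENCODE release 29 transcript with the longest coding sequence, then the longest 3′ UTR) were related to the fold changes by linear regression on length, GC content and mean expression with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Genes with no annotated 3′ UTR of at least 50 bases counted as not searched. The gene test was tested on simulated data for this comparison, with 200 of the 14237 genes changed in each of 5 runs. It recovered 30.3% of genes changed 1.5-fold, 64.6% of those changed 2-fold, 87.1% of those changed 4-fold and none of those changed 1.25-fold, with at most 5.02% false calls and none in the wrong direction. Camera found a list of 30 genes shifted by 0.3 in 20 of 20 runs with the preset and in 17 with an estimated correlation, with no false list. In both simulations the noise was drawn separately for each gene, and the simulated lists were random. The tested lists had estimated correlations of -0.04 to 0.90. These rates therefore do not cover false calls where genes move together. A word planted in shuffled fold changes ranked first of all words at each of 3 sizes.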

Results

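RNA was measured by poly(A) RNA sequencing in fibroblast-like synoviocytes, the fibroblasts of the joint lining, grown from synovial tissue of patients with rheumatoid arthritis. Cells were transfected with a pool of small interfering RNAs (siRNAs) against DLX4, a homeobox transcription factor, or with a non-targeting control siRNA, and were kept for 24 to 48 h before use. Each group had 3 libraries, lettered a to c. The question of the study was what DLX4 does for the invasiveness of these cells and for a set of cancer-related transcripts. The deposited values were FPKM (fragments per kilobase of gene, scaled to the depth of the library). The depth behind them, read from the whole-fragment steps of low values, was 23.6, 25.2 and 20.8 M fragments (M, mega) in control libraries a, b and c. It was 19.6, 21.7 and 23.7 M in DLX4 siRNA libraries a, b and c. At those depths 1 FPKM stood for 19.6 to 25.2 fragments per kilobase. The labels do not say that the libraries of a group came from separate cultures or donors, so p-values measure the spread between these libraries, which may be technical.

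DLX4 itself (ENSG00000108813) was close to the detection floor in every library. Control libraries a, b and c held 10, 9 and 2 DLX4 fragments (0.363, 0.307 and 0.0822 FPKM), and DLX4 siRNA libraries a, b and c held 0, 5 and 0 fragments (0, 0.198 and 0 FPKM). Summed over the groups, 21 control fragments stood against 5 with DLX4 siRNA, a ratio per depth of 0.255 with an exact 95% interval of 0.0751 to 0.695 that covers counting error only. A count of 0 allows up to 3 fragments, or 0.131 FPKM in DLX4 siRNA library a and 0.108 FPKM in library c. Between libraries the mean log2(FPKM + 1) was 0.32 in control and 0.09 in DLX4 siRNA libraries, which an exact two-sided permutation test did not separate (p = 0.2, where 3 against 3 libraries allow no p under 0.1). The limma fit across all genes gave a log2 fold change of -0.23 ± 0.17 (SE, adjusted p = 0.487, and 0.368 to 0.720 with 1 library left out). DLX3, a paralog of DLX4, fell from 3.62 ± 0.323 to 2.38 ± 0.0253 FPKM (SD, n = 3, adjusted p = 0.0273 by limma). That call was lost in all 6 fits that left out 1 library (adjusted p up to 0.0918). The 3′ untranslated region of DLX3 held the word CCATCT, which is described further on. DLX5 was at 2.55 ± 0.194 FPKM in control and 2.06 ± 0.285 FPKM in DLX4 siRNA libraries and DLX6 at 1.55 ± 0.393 FPKM in control and 1.254 ± 0.147 FPKM in DLX4 siRNA libraries (adjusted p = 0.305 and 0.566). DLX1 and DLX2 lay under the level filter, at 0.316 and 0.447 FPKM in control and 0.328 and 0.519 FPKM in DLX4 siRNA libraries on average.

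**Figure D1:**
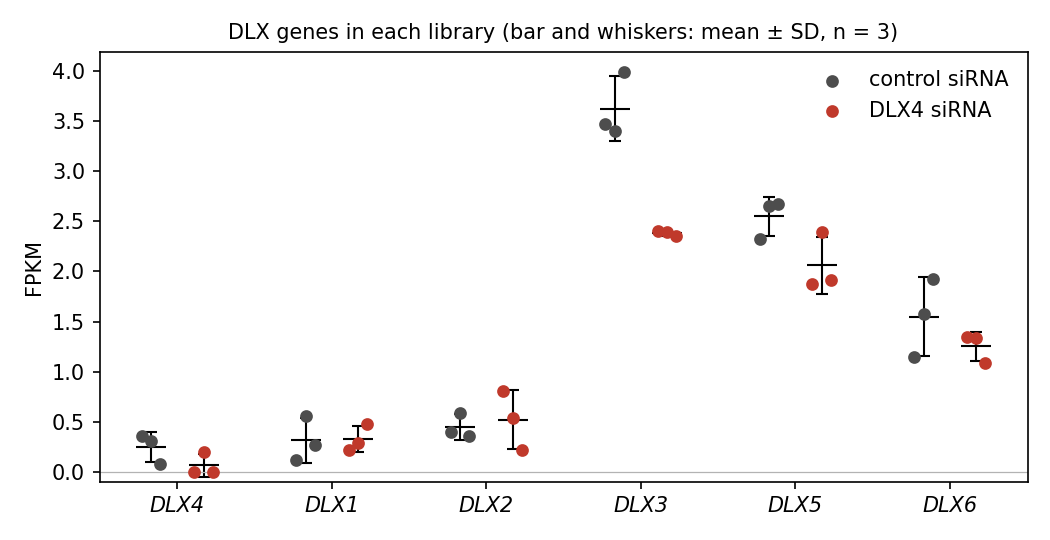
FPKM of the 6 DLX genes (vertical axis) in each library, grey points for control siRNA and red for DLX4 siRNA, with the mean and SD of the 3 libraries in black. DLX4 sits at or under 0.363 FPKM in all 6 libraries, and the 3 DLX4 siRNA libraries of DLX3 lie below its 3 control libraries.

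Across the transcriptome, more genes were lower than higher after DLX4 siRNA. Of 14237 genes tested, 1222 fell and 374 rose (limma, Benjamini-Hochberg adjusted p under 0.05). In all 1596 of them the 3 control libraries lay apart from the 3 DLX4 siRNA libraries, which the threshold itself favours. A fold of at least 2 on the log2(FPKM + 1) scale was reached by 114 of the lower and 12 of the higher genes. Groups lay apart in 30.4% of all genes tested, where 10% would do so by chance. The share of lower genes among the calls was 76.6%. It was 59.8% (871 lower, 585 higher) after quantile normalization and 64.9% (981 lower, 530 higher) after median-ratio scaling. After rescaling to the same sum it was 79.2% (1182 lower, 311 higher). The counts leaned on single libraries: leaving out control library a, b or c gave 666, 639 and 896 lower and 124, 135 and 242 higher genes, and leaving out DLX4 siRNA library a, b or c gave 1251, 694 and 723 lower and 433, 145 and 144 higher genes.

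ATP2B4, a calcium pump of the plasma membrane, fell 6.09-fold from 148 ± 16.3 to 24.3 ± 2.39 FPKM (SD, n = 3, adjusted p = 2.91e-05 by limma). SRM, the spermidine synthase, fell 4.96-fold from 193 ± 7.58 to 38.9 ± 2.39 FPKM (adjusted p = 1.13e-05). CPNE3, a calcium-dependent membrane-binding protein, fell from 108 ± 5.64 to 22.6 ± 1.30 FPKM. HADHA, a subunit of the enzyme of mitochondrial fatty acid oxidation, fell from 189 ± 7.31 to 44.9 ± 3.15 FPKM. CCBE1, a secreted factor of lymphatic vessel growth, fell from 55.1 ± 1.21 to 13.5 ± 0.396 FPKM. FADS2, a fatty acid desaturase, fell from 78.5 ± 3.77 to 22.6 ± 2.70 FPKM. TCF7, a transcription factor of the Wnt pathway, fell from 25.4 ± 2.03 to 6.75 ± 0.121 FPKM. ATP6V1F, a proton pump subunit, ACTL6A, a subunit of chromatin remodelling complexes, and the tetraspanin TSPAN11 fell 5.89-, 3.66- and 6.44-fold. All of these calls held in each of the 6 fits that left out 1 library. The 3′ UTRs (untranslated regions) of all 10 held the word CCATCT, which is described further on.

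HMOX1, the heme-degrading enzyme heme oxygenase, rose from 1133 ± 35.5 to 2923 ± 181 FPKM (SD, n = 3, 2.58-fold, adjusted p = 5.47e-05 by limma). CDKN2B, an inhibitor of cyclin-dependent kinases, rose 2.32-fold from 8.44 ± 0.662 to 19.6 ± 2.01 FPKM (adjusted p = 5.58e-04). SGPL1, the sphingosine phosphate lyase, rose from 13.4 ± 2.19 to 27.9 ± 2.06 FPKM, RMND5A, part of a ubiquitin ligase, from 12.2 ± 1.61 to 24.9 ± 1.61 FPKM, and TNFRSF10D, a decoy receptor for the death ligand TRAIL, from 21.5 ± 1.43 to 42.2 ± 3.96 FPKM. TSPAN2, a tetraspanin, rose from 0.621 ± 0.195 to 2.71 ± 0.238 FPKM. Short or non-coding RNAs also stood among the 12 lowest (MIR3181 and MT-TS1) and the 12 highest (MIR27A, SNORD19C, SNORD62B, MALAT1, MXRA7P1 and a Y RNA). The calls of MT-TS1 (adjusted p = 0.0612 without control library b), MALAT1, the Y RNA, SNORD19C, SNORD62B and MXRA7P1 were lost in 1, 2, 3, 3, 4 and 5 of the fits that left out 1 library, with adjusted p up to 0.144. Poly(A) libraries read such RNAs poorly, several lie inside other genes, and the strand setting of the counting is not given in the sources used here, so their values are uncertain.

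**Figure D2:**
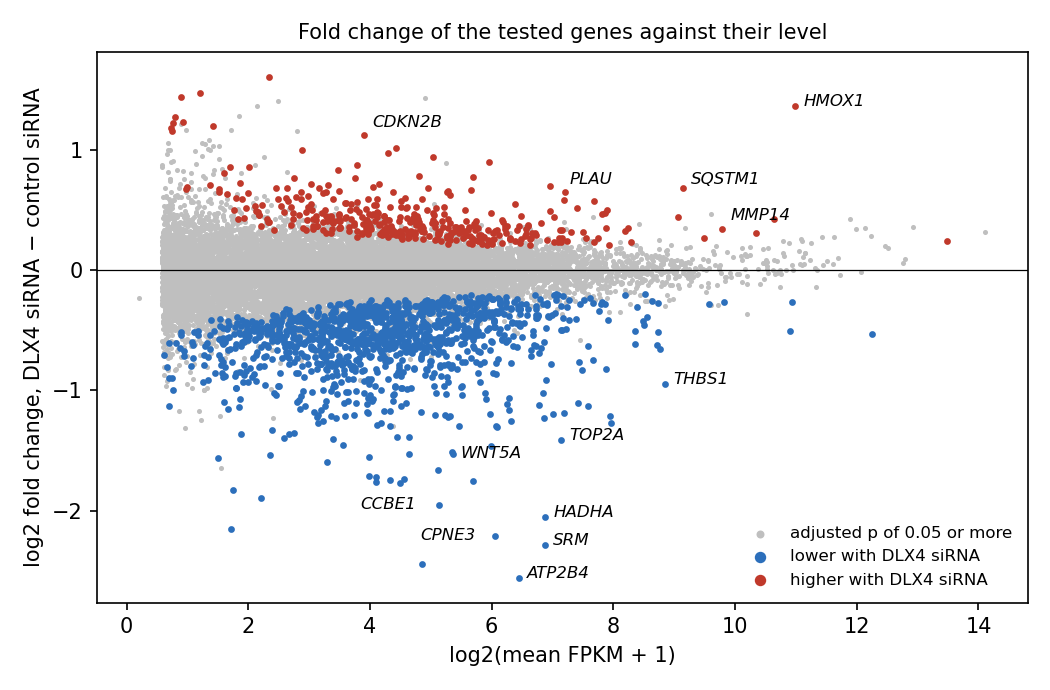
Log2 fold change of each of the 14237 tested genes (vertical axis) against its log2(mean FPKM + 1), with genes past the limma threshold in blue (lower) and red (higher) and the rest in grey. The blue points reach down to -2.56 for ATP2B4, and HMOX1 lies at 1.37.

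Genes of cell division fell together. In the list for mitosis and G2/M, 36 of 40 members fell, none rose, and the median log2 fold change was -0.65. TOP2A, the topoisomerase that untangles replicated chromosomes, fell from 205 ± 7.89 to 76.5 ± 4.85 FPKM (SD, n = 3, adjusted p = 5.12e-05 by limma). CDC20, an activator of the anaphase-promoting complex, fell from 45.7 ± 0.308 to 24.4 ± 1.49 FPKM, the spindle protein TPX2 from 44.1 ± 0.296 to 25.1 ± 1.61 FPKM and the cytokinesis scaffold ANLN from 135 ± 2.95 to 83.5 ± 3.70 FPKM. MKI67, the proliferation marker, fell from 50.2 ± 10.4 to 24.1 ± 5.45 FPKM (adjusted p = 0.0111, and 0.0510 without DLX4 siRNA library c). In the list for DNA replication and G1/S, 27 of 39 members fell, none rose, and the median was -0.53. The replicative helicase subunit MCM2 fell 1.94-fold to 25.8 ± 1.55 FPKM and MCM3, another subunit, from 46.8 ± 1.40 to 30.4 ± 0.639 FPKM, the DNA polymerase POLE from 27.3 ± 1.42 to 12.8 ± 0.963 FPKM and the DNA ligase LIG1 from 30.4 ± 0.995 to 19.3 ± 1.24 FPKM. Adjusted over the list alone, 39 of the mitosis and 36 of the replication members fell. Camera with a preset correlation of 0.01 called both lists (adjusted p = 2.53e-25 and 3.22e-19), and neither was called with an estimated correlation (adjusted p = 0.107 with an estimated correlation for each). The 3′ UTR held CCATCT in 8 of the 36 lower mitosis genes and 9 of the 27 lower replication genes, TOP2A, MKI67 and POLE among them. Among genes with no CCATCT in any transcript camera called both lists, with a median of -0.59 over 10 mitosis members (adjusted p = 1.27e-12) and -0.51 over 15 replication members (adjusted p = 2.51e-16). In that fit 4 of these mitosis and 6 of these replication members passed limma, all lower. Camera used the preset correlation there, and an estimated one was not run on these genes.

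In the list for ribosome production, a process that MYC drives, 5 of 27 tested members fell, none rose and 22 did not pass the test. The median log2 fold change was -0.20 (camera adjusted p = 2.16e-04, and adjusted p = 0.207 with an estimated correlation), and 12 fell when adjusted over the list alone. Among the 5 members with no CCATCT in any transcript none fell, and the camera call was lost (median -0.04, adjusted p = 0.762, with 8.29e-07 to 0.762 over all alternatives). SRM, the lowest of the 5, is the spermidine synthase and not itself a factor of ribosome production. DKC1, the pseudouridine synthase of ribosomal RNA, fell from 46.3 ± 1.32 to 27.8 ± 2.07 FPKM (SD, n = 3). NCL and WDR43, factors of the nucleolus, had log2 fold changes of -0.20 and -0.26 with adjusted p of 0.0425 and 0.0239 by limma. Each lost its call in 5 of the 6 fits that left out 1 library, all but the fit without DLX4 siRNA library a (adjusted p up to 0.156 and 0.0894). MYC itself was at 28.0 ± 1.28 FPKM in control and 24.5 ± 1.23 FPKM in DLX4 siRNA libraries (adjusted p = 0.147). Of the 5 lower members, 3 held CCATCT in the 3′ UTR, SRM, DKC1 and NCL.

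Genes of the oxidative stress response that NRF2 controls went both ways. Of 25 members 6 rose and 2 fell, and the median was 0.02 (camera adjusted p = 0.0175, and adjusted p = 0.419 with an estimated correlation). The median was 0.04, 0.05 and 0.04 without control library a, b or c and 0.03 and 0.06 without DLX4 siRNA library a or c, and the list had median log2 differences of -0.05 between control library c and controls a and b and -0.11 between DLX4 siRNA library a and libraries b and c. The median was 0.0038 after rescaling to the same sum, 0.06 after median-ratio scaling and 0.09 after quantile normalization. With p-values adjusted over the list alone, 7 rose and 3 fell. Besides HMOX1, SQSTM1, an autophagy receptor, rose from 432 ± 5.59 to 694 ± 14.2 FPKM and SLC7A11, the cystine transporter, from 17.7 ± 0.669 to 25.99 ± 1.01 FPKM (SD, n = 3). The ferritin light chain FTL fell from 5763 ± 85.5 to 3988 ± 301 FPKM, a call that was lost when no low genes were removed. Of 29 genes of unfolded protein and amino acid stress, 8 rose and 3 fell (median 0.04, camera adjusted p = 0.0175, and adjusted p = 0.638 with an estimated correlation). The camera call was lost without control library c, DLX4 siRNA library b or DLX4 siRNA library c (adjusted p = 0.0855, 0.0644 and 0.0557) and after quantile normalization (0.0694), with 0.00182 to 0.638 over all alternatives. The median was 0.0086 without DLX4 siRNA library b, 0.02 without DLX4 siRNA library c, 0.13 without DLX4 siRNA library a and 0.09 without control library b. Among the 9 members with no CCATCT the call held at a median of 0.26 (adjusted p = 0.0140). The list had median log2 differences of -0.08 between control library c and controls a and b and -0.15 between DLX4 siRNA library a and libraries b and c. The median was 0.03, 0.09 and 0.10 after the same 3 rescalings. With p-values adjusted over the list alone, 8 rose and 3 fell. The amino acid transporter SLC7A5 rose from 93.6 ± 2.47 to 153 ± 7.66 FPKM and the stress pseudokinase TRIB3 from 21.1 ± 0.744 to 30.8 ± 2.02 FPKM. EDEM1, which clears misfolded proteins from the endoplasmic reticulum and holds CCATCT in its 3′ UTR, fell from 30.6 ± 4.12 to 11.1 ± 1.27 FPKM. Of 33 genes of hypoxia and glycolysis, 6 rose and 2 fell (median 0.08, camera adjusted p = 2.16e-04, and adjusted p = 0.209 with an estimated correlation). The median was 0.12 after median-ratio scaling. With p-values adjusted over the list alone, 8 rose and 2 fell. Among genes with no CCATCT only 5 members were tested and the call was lost at a median of 0.09 (adjusted p = 0.374, with 2.78e-05 to 0.374 over all alternatives). The hexokinase HK2 rose from 15.2 ± 0.578 to 24.5 ± 1.07 FPKM, the glucose transporter SLC2A3 from 22.2 ± 0.555 to 33.9 ± 1.40 FPKM and the enolase ENO2 from 26.9 ± 0.480 to 39.1 ± 2.98 FPKM. The lower members, MXI1 and PDK1, were named after their values were seen and fell by 0.64 and 0.58 on the log2 scale. The 3′ UTR held CCATCT in 2 of the 2 lower and 2 of the 6 higher members.

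Proteases and their inhibitors bear on invasion, which these cells carry out in the joint. Of 27 matrix-degrading proteases tested, 5 rose, 1 fell and 21 did not pass the test (median 0.10, camera adjusted p = 0.00875, and adjusted p = 0.419 with an estimated correlation, and 0.0593 after quantile normalization, with 1.06e-04 to 0.419 over all alternatives). The median was 0.03 without control library c, 0.04 without DLX4 siRNA library c and 0.17 without DLX4 siRNA library a, and among the 6 members with no CCATCT the call was lost at a median of 0.09 (adjusted p = 0.374). The list had median log2 differences of -0.07 between control library c and controls a and b and -0.07 between DLX4 siRNA library a and libraries b and c. With p-values adjusted over the list alone, 6 rose and 2 fell. PLAU, the urokinase that activates plasminogen, rose from 114 ± 9.62 to 179.9 ± 14.9 FPKM (SD, n = 3, adjusted p = 0.00359 by limma) and kept its call with any library left out. MMP14, a membrane-bound collagenase, rose from 775 ± 26.5 to 987 ± 86.6 FPKM (adjusted p = 0.0278), ADAM17, a sheddase, from 15.2 ± 0.929 to 20.4 ± 1.74 FPKM and ADAMTS1, a proteoglycanase, from 286 ± 1.13 to 336 ± 6.66 FPKM. ADAM12, a disintegrin metalloprotease with CCATCT in its 3′ UTR, fell from 417 ± 27.1 to 305 ± 28.0 FPKM. Of the 5 higher proteases 3 also held the word there. MMP14 and ADAMTS1 lost their calls in 5 of the 6 fits that left out 1 library, all but the fit without DLX4 siRNA library a. ADAM17 lost its call without control library b, control library c or DLX4 siRNA library c, and ADAM12 without control library b, DLX4 siRNA library b or DLX4 siRNA library c. With 1 library left out, the largest adjusted p was 0.114 for MMP14, 0.0949 for ADAM17, 0.107 for ADAMTS1 and 0.0593 for ADAM12. The collagenase MMP1 was at 5.03 ± 0.243 FPKM in control and 5.01 ± 1.02 FPKM in DLX4 siRNA libraries and the stromelysin MMP3 at 11.9 ± 1.95 FPKM in control and 11.1 ± 2.03 FPKM in DLX4 siRNA libraries (adjusted p = 0.959 and 0.792). MMP13 had at most 0.0759 FPKM in a control library and was listed at 0 in all DLX4 siRNA libraries. Among 14 protease inhibitors 2 rose and 1 fell (camera adjusted p = 0.113), with TIMP3 higher (1164 ± 40.7 to 1442 ± 64.7 FPKM, adjusted p = 0.0177, lost without control library a or b or DLX4 siRNA library b or c, up to 0.0951) and TIMP1 at 1532 ± 203 FPKM in control and 1643 ± 335 FPKM in DLX4 siRNA libraries.

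Of 19 targets and feedback genes of NF-kB, a transcription factor of inflammation, 4 rose and none fell (median 0.11, camera adjusted p = 0.0118, and adjusted p = 0.209 with an estimated correlation). With p-values adjusted over the list alone, 4 rose and 2 fell. NFKB2, a subunit of NF-kB, rose from 21.2 ± 0.0744 to 28.4 ± 0.593 FPKM (SD, n = 3) and IER3, an early response gene, from 11.5 ± 1.00 to 17.9 ± 2.10 FPKM, with adjusted p of 0.00470 and 0.0106 by limma. The other higher members lost their calls, NFKBIZ in all 6 fits that left out 1 library (adjusted p up to 0.129) and BIRC3 without control library a or b or DLX4 siRNA library b (up to 0.0828). The list median was 0.19 after quantile normalization. The inflammatory cytokine IL6 was at 2.92 ± 0.774 FPKM in control and 4.99 ± 1.85 FPKM in DLX4 siRNA libraries, CXCL8 at 6.59 ± 1.52 FPKM in control and 5.46 ± 1.38 FPKM in DLX4 siRNA libraries and CCL2 at 31.1 ± 6.29 FPKM in control and 36.5 ± 8.46 FPKM in DLX4 siRNA libraries, with adjusted p of 0.203, 0.517 and 0.581. Of 25 genes of the response to TGF-beta, 3 rose and 2 fell (median 0.07, camera adjusted p = 0.0458, and adjusted p = 0.296 with an estimated correlation). The camera call was lost without control library a or DLX4 siRNA library a, b or c (adjusted p = 0.138, 0.0709, 0.0595 and 0.0557), and it held in 13 of 24 settings, with 0.0127 to 0.296 over all alternatives. The median was 0.04 without DLX4 siRNA library a and 0.11 after median-ratio scaling, and among the 8 members with no CCATCT the median was 0.22 and the call was lost (adjusted p = 0.109). With p-values adjusted over the list alone, 4 rose and 2 fell. BHLHE40, a transcriptional repressor, rose from 33.4 ± 1.68 to 44.1 ± 0.720 FPKM and CCN2, a matricellular protein, from 94.5 ± 3.28 to 116 ± 7.31 FPKM (adjusted p = 0.0291, lost without any 1 library other than DLX4 siRNA a, up to 0.112). SKI, a corepressor of the pathway with CCATCT in its 3′ UTR, fell from 154 ± 20.1 to 81.7 ± 10.4 FPKM.

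**Figure D3:**
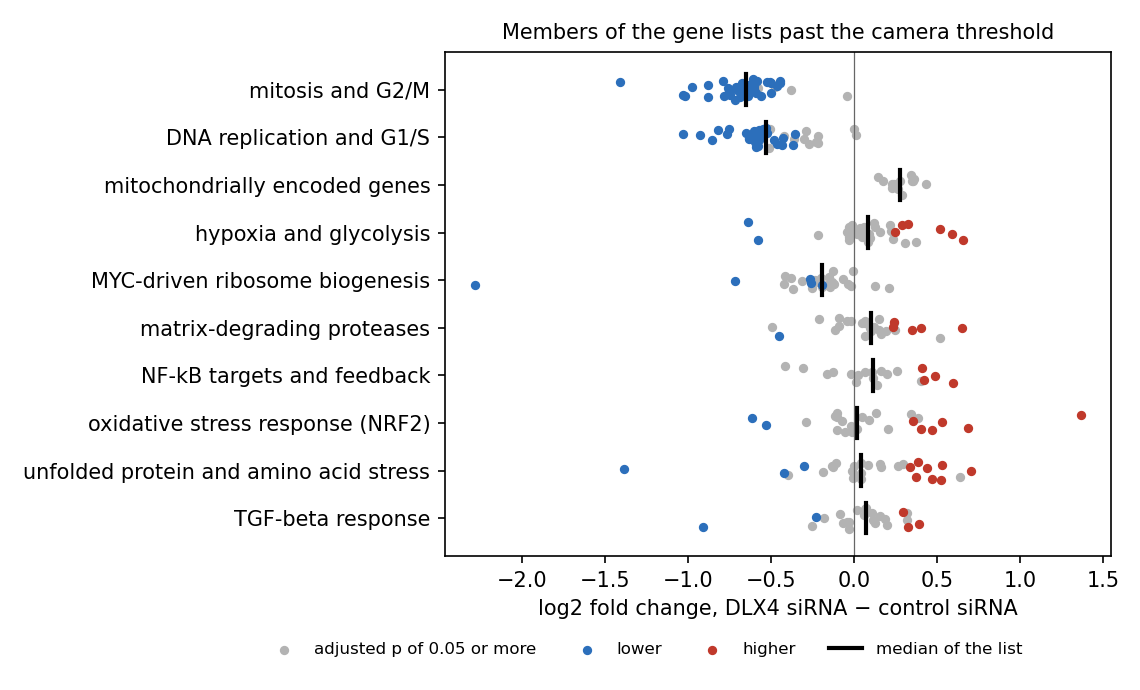
Log2 fold change (horizontal axis) of each tested member of the 10 gene lists past the camera threshold with a preset correlation, blue where the gene was lower, red where it was higher and grey where it did not pass limma, with the list median as a black bar. The medians run from -0.65 for mitosis and G2/M to 0.28 for the mitochondrially encoded genes.

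Genes tied to DLX4 in work on tumours, taken from textbook knowledge and not from these samples, moved in both directions. Of 9 tested, 3 rose and 2 fell (camera adjusted p = 0.427), and adjusted over the list alone 4 rose and 4 fell. Besides CDKN2B, the cell cycle inhibitor CDKN1A rose from 449 ± 19.5 to 612 ± 33.2 FPKM and the growth factor FGF2 from 64.5 ± 0.970 to 83.3 ± 1.94 FPKM (SD, n = 3, adjusted p = 0.00492 and 0.00492 by limma). BRCA1, a DNA repair gene, fell from 17.2 ± 0.944 to 10.2 ± 0.210 FPKM and TWIST1, a transcription factor of mesenchymal cells, from 53.7 ± 1.64 to 43.8 ± 2.92 FPKM (adjusted p = 0.00108 and 0.0349, the latter lost without any 1 library other than DLX4 siRNA a, up to 0.130). CDKN2B, CDKN1A, FGF2 and TWIST1 held no CCATCT in the 3′ UTR, and BRCA1 held it. The angiogenic factor VEGFA was at 80.2 ± 3.50 FPKM in control and 90.4 ± 11.2 FPKM in DLX4 siRNA libraries (adjusted p = 0.346).

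Fibroblast markers named in advance did not pass the test. PRG4, the lubricin of the joint lining, was at 187 ± 8.36 FPKM in control and 172 ± 4.45 FPKM in DLX4 siRNA libraries, the fibroblast marker THY1 at 507 ± 28.0 FPKM in control and 466 ± 42.4 FPKM in DLX4 siRNA libraries and fibronectin FN1 at 6778 ± 309.8 FPKM in control and 7075 ± 545 FPKM in DLX4 siRNA libraries (n = 3, adjusted p = 0.254, 0.407 and 0.720 by limma). COL1A1 was at 15736 ± 1054 FPKM in control and 19655 ± 1752 FPKM in DLX4 siRNA libraries (adjusted p = 0.0686), and its difference was 0 after quantile normalization, under which that of FN1 turned sign. Of the 10 lining markers tested 1 fell, the guidance factor SEMA3C, from 385 ± 9.52 to 271 ± 4.07 FPKM, and of the 17 sublining markers none passed the test. The 3′ UTR of SEMA3C held CCATCT. Macrophage markers were low in every library, with CD74 highest at 17.9 FPKM on average and the macrophage list summing to 22.3 to 25.5 FPKM. Lymphocyte markers summed to 7.73 to 11.1 FPKM, epithelial markers to 6.59 to 10.3 FPKM and adipocyte markers to 7.83 to 10.4 FPKM. Pericyte and smooth muscle markers summed to 145 to 169 FPKM, endothelial markers to 44.9 to 54.5 FPKM and chondrocyte and osteoblast markers to 29.3 to 42.8 FPKM. NDUFA4L2, TEK and ACAN were highest in them (78.2, 38.5 and 26.9 FPKM). In these lists ERG fell from 3.78 to 2.26 FPKM and RUNX2 from 3.46 to 2.28 FPKM (limma adjusted p = 0.0103 and 0.0470). ERG lost its call without control library b and RUNX2 without any 1 library other than DLX4 siRNA a.

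Control library c and DLX4 siRNA library a stood apart from the other libraries of their groups. The groups parted on the first principal component (42.2% of the variance) and these 2 libraries parted from the rest on the second (26.1%), at -16.0 and -21.9 against 8.96 to 9.98 in the other libraries. The 13 mitochondrially encoded genes moved with them. No member passed limma, the list median was 0.28 (camera adjusted p = 2.16e-04, and adjusted p = 0.638 with an estimated correlation), and the same list had a median log2 difference of -0.41 between control library c and controls a and b and of -0.29 between DLX4 siRNA library a and libraries b and c. The list median was 0.17 without control library c and 0.14 after quantile normalization (adjusted p = 0.0359, with 1.16e-12 to 0.638 over all alternatives), and among the 8 members with no CCATCT the call held at 0.25 (adjusted p = 0.0140). The 47 cytosolic ribosomal protein genes, of which none passed limma (median -0.02), had medians of -0.26 and -0.34 in the same 2 libraries. The mitosis list had medians of -0.06 and -0.16 there and the replication list -0.05 and -0.09, and the list of ribosome production -0.06 and -0.11. Without both libraries, a choice made after seeing the data, 1841 genes were lower and 940 higher, 1132 and 347 of them shared with the counts from all 6 libraries, and the mitosis and replication medians were -0.64 and -0.47.

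**Figure D4:**
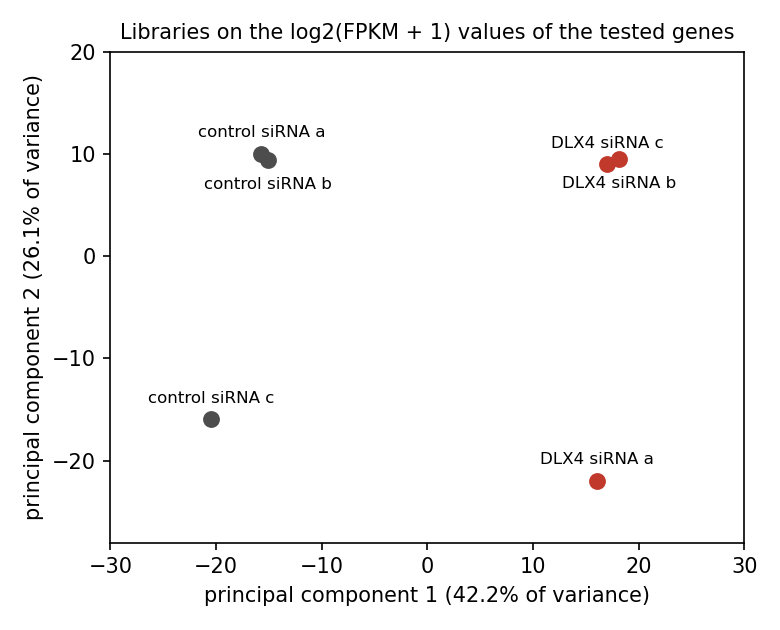
The 6 libraries on the first and second principal components of log2(FPKM + 1) over the tested genes, grey for control siRNA and red for DLX4 siRNA. The groups part along the horizontal axis (42.2% of the variance), and control c and DLX4 siRNA a lie at -16.0 and -21.9 on the vertical axis (26.1%).

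Fold changes were also compared with the short words in the 3′ UTRs of the genes, a choice made after the data were seen. Among 11650 tested genes with an annotated 3′ UTR of at least 50 bases, 16148 words of 7 bases were ranked by the t of their coefficient on the log2 fold change, adjusted for UTR length, GC content and expression. ACCATCT ranked lowest (coefficient -0.20, t = -23.9, 1218 genes), while the highest t of any word was 5.2. GCCATCT came next (coefficient -0.155, t = -18.8, 1288 genes), and no annotated DLX4 transcript held it. CCATCTA followed (t = -16.3), while TCCATCT and CCCATCT had coefficients of -0.0665 and -0.0566. Genes were grouped by their best match to ACCATCT, so the 6mer group can hold genes with GCCATCT, TCCATCT or CCCATCT. The median log2 fold change was -0.23 for the 206 genes with ACCATCT followed by A (8mer), -0.15 for the other 1012 genes with ACCATCT (7mer-m8), -0.10 for the 510 genes with CCATCT followed by A (7mer-A1), -0.05 for the 2696 genes with CCATCT alone (6mer) and -0.01 for the 7226 genes with none. The shares of lower genes were 34.0%, 24.7%, 17.1%, 12.2% and 5.84%, and those of higher genes lay between 1.88% and 3.11%. CCATCT occurred in the 3′ UTR of 63.6% of the lower genes, 85.2% of the genes lower by at least 2-fold, 33.0% of the higher genes and 35.2% of the genes not called. WNT5A, a Wnt ligand with an 8mer site, fell from 59.6 ± 9.37 to 20.3 ± 3.71 FPKM (SD, n = 3), the integrin ITGB3 and the matricellular protein THBS1, both with 7mer-m8 sites, from 36.2 ± 1.68 to 11.9 ± 0.511 and from 602 ± 54.4 to 314 ± 44.5 FPKM. Higher genes held sites too, ADAMTS1 an 8mer, SGPL1, MMP14 and TIMP3 a 7mer-m8, HK2 a 7mer-A1 and TNFRSF10D, TSPAN2, SLC7A11 and IER3 a 6mer site. The lower genes CDC20, TPX2, ANLN, MCM2, MCM3, LIG1, WDR43, FTL and TWIST1 held none in the 3′ UTR searched. Of these, only ANLN, MCM3 and TWIST1 held no CCATCT in any annotated transcript. The 1000 genes with ACCATCT in the coding sequence alone had a median of -0.07, with 10.7% lower. With no CCATCT the median was 0.02, with 4.07% lower. The median was -0.0011 for the 56 genes with ACCATCT in the 5′ UTR alone. AXL, a receptor tyrosine kinase, and BAX, an apoptosis effector, both with 7mer-m8 sites, fell from 253 ± 26.4 to 152 ± 26.3 and from 80.1 ± 4.07 to 38.2 ± 8.52 FPKM.

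**Figure D5:**
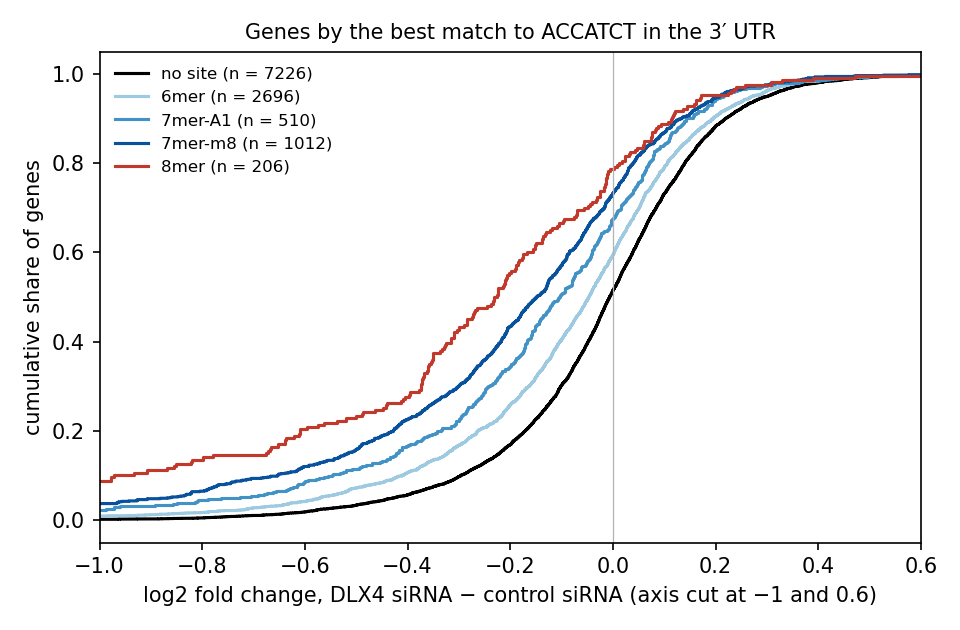
Cumulative share of genes (vertical axis) by log2 fold change (horizontal axis, drawn from -1 to 0.6), 1 line for each kind of best match to ACCATCT in the 3′ UTR. The medians are -0.23 for 8mer, -0.15 for 7mer-m8, -0.10 for 7mer-A1, -0.05 for 6mer and -0.01 for genes with no site.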

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

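The fits on genes with no CCATCT, without control c and DLX4 siRNA a together, with a term for them, and with voom were chosen after seeing the data, and the other alternatives before. No called gene passed the threshold in the opposite direction in any alternative run. Signs were followed only for the genes that the naming rule picked and for the lists. None of those genes that was called and none of the 10 lists called by camera turned direction, though quantile normalization put COL1A2 at 0, since it ranked alike in all libraries. Lists not called did turn on genes with no CCATCT, those of the Wnt pathway, YAP/TAZ targets, p53 targets and the actin cytoskeleton from lower to higher and those of collagens and cytosolic ribosomal proteins from higher to lower (adjusted p of 0.221 to 0.762). The cause of the differences below was not tested unless given. Higher genes, 374 as reported, numbered 230 with no level filter (more genes tested), 585 after quantile normalization, 846 with array weights and 74 with a replicate block. They numbered 65 at a fold of at least 1.5 and 95 at an adjusted p under 0.01. Among the 3407 genes with no CCATCT they numbered 21 when fitted alone and 86 when all genes were fitted. DLX4, which holds CCATCT, was kept in that fit and is counted among these genes. There were 940 without control c and DLX4 siRNA a together, 1290 with a term for them, and 124 (without control a) to 433 (without DLX4 siRNA a) with 1 library left out. Lower genes, 1222 as reported, numbered 1948 with array weights, 522 with a replicate block, 502 at a fold of at least 1.5 and 575 at an adjusted p under 0.01. Among genes with no CCATCT they numbered 34 when fitted alone and 111 when all genes were fitted. There were 1841 without both libraries, 2394 with the term, and 639 (without control b) to 1251 (without DLX4 siRNA a) with 1 library left out. The replicate block pairs the libraries by letter. The values gave no ground for that pairing, since libraries a, b and c of the 2 groups had correlations of -0.24, 0.16 and -0.23 in their deviations from the group means. Lists higher, 7 as reported, numbered 4 after quantile normalization, 0 with an estimated correlation, 2 among genes with no CCATCT and 5 to 8 with 1 library left out. Lists lower, 3 as reported, numbered 0 with an estimated correlation, 2 among genes with no CCATCT and 3 with any library left out. Over lists of both directions, the smallest adjusted p with an estimated correlation was 0.107, 5 lists had an unadjusted p under 0.05 with it, and 13 passed fry. DLX4 kept its direction and did not pass the threshold in any alternative. Of the 148 tested genes that the naming rule picked 117 were called, 73 of them with each library left out and 62 under every setting run, and 16 of the 31 not called passed under some setting. Depth limits DLX4 itself, since 3 fragments were 0.102 to 0.131 FPKM.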

Other observations

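The tests of the 3′ UTR words, of transcript length, of exchanged labels and of the proliferation state were chosen after the results they measure were seen, the test of genes free of the word was chosen after seeing the data but before its counts, and those of library scaling and of other splits were not. Several gene groups without a camera call held members that passed limma. Of 34 interferon-stimulated genes 6 fell and none rose (median -0.14, camera adjusted p = 0.114, adjusted p = 0.380 with an estimated correlation, fry adjusted p = 8.29e-04), among them OAS3, an antiviral RNA sensor, from 38.0 ± 2.72 to 25.3 ± 1.76 FPKM, and the antiviral protein TRIM22, from 55.2 ± 4.003 to 38.3 ± 3.35 FPKM (SD, n = 3). GBP1, an interferon-induced GTPase, fell from 14.7 ± 0.647 to 9.37 ± 1.37 FPKM, with an adjusted p of 0.0580 without control library a. Of 34 genes of integrins and focal adhesion 5 fell and none rose (median -0.01, camera adjusted p = 0.590), with FERMT2, an activator of integrins, from 94.6 ± 5.25 to 37.9 ± 3.96 FPKM and the integrin ITGA1 from 13.7 ± 0.284 to 8.44 ± 0.244 FPKM. Of 34 genes of the actin cytoskeleton and cell migration 4 fell and none rose (median -0.01, camera adjusted p = 0.876), with ACTN1, an actin crosslinker, from 261 ± 16.0 to 119 ± 9.16 FPKM and the formin DIAPH3 from 18.1 ± 0.577 to 9.73 ± 0.615 FPKM. The 3′ UTR held CCATCT in 4 of the 6 lower interferon genes, OAS3 and TRIM22 among them, and over the 6 list members with no CCATCT in any transcript the median was -0.06 and none fell (camera adjusted p = 0.690). ITGB3, ITGA1, FERMT2, ACTN1 and DIAPH3 all held CCATCT in the 3′ UTR.

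Of 29 genes of the Wnt pathway 1 rose and 4 fell (camera adjusted p = 0.779), with the receptor FZD6, which holds an 8mer site, from 18.0 ± 0.989 to 10.9 ± 0.847 FPKM besides TCF7 and WNT5A. Of 26 p53 targets 4 rose and 5 fell (camera adjusted p = 0.779), with the stress regulator TP53INP1 higher (7.32 ± 0.371 to 11.6 ± 0.626 FPKM) and the death receptor TNFRSF10B lower (59.4 ± 2.33 to 30.01 ± 0.564 FPKM). Of 26 apoptosis regulators 2 rose and 4 fell (camera adjusted p = 0.779), with PMAIP1, a promoter of apoptosis, from 3.93 ± 0.213 to 1.24 ± 0.155 FPKM and BIRC2, an inhibitor of apoptosis, from 56.1 ± 1.08 to 32.7 ± 2.62 FPKM. The 3′ UTR held CCATCT in 4 of the 4 lower Wnt, 4 of the 5 lower p53 and 3 of the 4 lower apoptosis genes. TNFRSF10B and BIRC2 were among them, and PMAIP1 held none there. Of the higher genes, 0 of 1 Wnt, 1 of 4 p53 and 2 of 2 apoptosis genes held it. Of 18 inflammatory cytokines and chemokines 2 fell and none rose, while the list median was 0.05 and the camera direction was higher (adjusted p = 0.393). PTGES, a prostaglandin synthase with a 7mer-m8 site, fell from 2.14 ± 0.261 to 0.901 ± 0.146 FPKM. The other lower member, CXCL1, held no CCATCT and lost its call in all 6 fits that left out 1 library (limma adjusted p up to 0.123). Median, mean and camera direction differed in sign for the lists of apoptosis regulators, collagens, immediate early genes, cytosolic ribosomal proteins, ERK output, lining markers and sublining markers, none of which camera called.

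More genes were lower than higher with DLX4 siRNA, and a candidate explanation is a match between the seed of an siRNA guide and 3′ UTRs. Genes with an 8mer site had a median log2 fold change -0.22 relative to genes with none, but the word was chosen from the same fold changes, a choice that did not fix the medians of genes with CCATCT and no ACCATCT (-0.10 for 7mer-A1 and -0.05 for 6mer sites, against -0.01 for none) nor its t between libraries of 1 group (at most 1.14 in size), and the siRNA sequences are not given in the sources used here. Annotated DLX4 transcripts themselves held the 8mer site, ACCATCTA, in the coding sequence, and 5.21% of all 8-base words occur in DLX4. A guide against DLX4 with this seed is therefore possible, but the site does not show that the pool held one. Library scaling stays open, since 1.49 genes were lower per higher gene after quantile normalization, between the bounds set for and against it. Loss of DLX4, the biological explanation, stays open as a part of the cause. Of 3407 genes with no CCATCT in any annotated transcript (DLX4, which holds it, counted with them), 55 were called when fitted alone (34 lower, 21 higher). This met the prediction as first written. It cannot tell loss of DLX4 from a seed match, since genes without the word could also change in the wake of genes that hold it. With all genes fitted, 111 of these genes were lower and 86 higher, against 1222 and 374 of all 14237. That difference in split was not tested. Genes with no CCATCT were called less often than the others (5.78% against 12.9%), a condition added after the counts were seen. Searched genes with CCATCT in the 3′ UTR split into 736 lower and 111 higher, those with no CCATCT in the searched transcript into 163 and 143. With the order of medians by site, this argues against loss of DLX4 as the only cause of the excess, though the word came from the same fold changes. DLX4 was read in 21 and 5 fragments, and how much its loss adds cannot be told apart from the seed match.

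The 1596 calls were also set against other ways to part the 6 libraries into 3 and 3. Of the 10 splits, 1 (the real one) gave as many calls and the highest of the others gave 0 at the limma threshold. With 10 splits the share cannot fall under 0.05.

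Control library c and DLX4 siRNA library a stood apart from their groups in the same direction, and a bias by transcript length may account for part of it. Across genes, which are not independent replicates, the shift of control c and of DLX4 siRNA a had Spearman rho of 0.367 and 0.411 with transcript length (97.2% of genes with a length). An exchange of these labels was argued against by 2781 genes called from the other 4 libraries, on which control c lay at 0.0332 and DLX4 siRNA a at 0.877 between the control mean (0) and the DLX4 siRNA mean (1). A different proliferation state stays open, since the length-adjusted median of the mitosis list was -0.0942 in DLX4 siRNA a (bootstrap 95% interval -0.130 to -0.0225) and -0.0299 in control c (-0.0978 to 0.0163). The labels give no batch.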
